A study of Mus musculus with 24 samples.

How the data were processed

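RNA abundance was measured on Affymetrix mouse genome arrays in 24 samples of mouse cells. The samples form 12 groups of 2, and 6 groups were labelled with the standard protocol (unamplified arrays) while the other 6 were first amplified by PCR (amplified arrays). Per the labels, amplified samples started from 5 ng of total RNA, corresponding to 500 cells, and went through 22 cycles of PCR. The labels call the members of each group biological replicates but do not say whether they were separate cultures or litters, so p-values measure the spread between these samples.

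The deposited table gives 1 intensity per probe set and array, on a linear scale, for 45101 probe sets. Its lowest value is 1 and its highest is 17519. The software and the normalization behind the deposited intensity values are not given in the sources used here. A total signal per array says little about depth on arrays, and the number of arrays limits the precision. The median intensity lay between 41.1 and 49.2 on the 12 unamplified arrays and between 36.2 and 40 on the 12 amplified arrays, and the log2 medians spanned 0.26 and 0.15 within these sets. Both spans were under a limit of 0.5 set beforehand, so the values were used as deposited, without further scaling.

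Probe sets were assigned to genes with the annotation of the array. A single gene symbol was listed for 34958 probe sets, 932 were listed with several symbols, 9211 were not listed, and 64 were Affymetrix controls. Gene IDs of 34754 probe sets matched a RefSeq gene table for the mouse genome build GRCm38.p6, 204 had no match, and 0 symbols changed. Probe sets with several symbols or none were left out of gene results, which left 18194 genes. Each gene was represented by its probe set with the highest mean log2 intensity over the 24 arrays. Brachyury (T) and Nanos3 had no probe set listed for them alone and were not analysed here.

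Values below the 10th percentile of the table, 4.2, were raised to it, and log2 was taken. Genes were tested where at least 2 of the 12 arrays of a set exceeded the 40th percentile of that set, which was 28.1 for unamplified and 24 for amplified arrays. This left 14934 genes on unamplified arrays, 15608 on amplified arrays and 14553 on both. Differences between groups were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays of a set, moderated variances with an intensity trend, and 6 residual degrees of freedom. Amplified and unamplified arrays were fitted together only to ask whether a difference depended on amplification. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called where the adjusted p was under 0.05 and the log2 difference was at least 1 in size, a fold of 2. Differences are given as log2 ± standard error, with n = 2 arrays per group. Where the group with the lower signal lay below the filter level, the fold was computed against that level and is given as "at least".

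Before the data were examined, the comparisons, the thresholds, 26 gene lists with 416 genes and a rule for naming genes were set down. On the array, 383 of the list genes were named. The rule took, for each of 8 main comparisons, the 6 called genes with the largest increase and the 6 with the largest decrease whose arrays did not overlap between groups, up to 4 called members of each list with at least 3 called members, and a fixed set of pluripotency and germ cell genes. Provisional gene names were passed over. Genes named outside this rule are said to have been chosen after their values were seen. List shifts were tested with the competitive camera test of limma on moderated t statistics, adjusted over the 26 lists, with a preset correlation between genes of 0.01. The test was repeated with a correlation estimated from the data for each list. That repeat also uses only the 6 residual degrees of freedom, so its p-values can be larger without a higher correlation. For fibroblast markers in EpiSCs minus day 2 EpiLCs on unamplified arrays, the estimated correlation was -0.008. The unadjusted camera p was 5.77e-14 at the preset correlation and 0.00069 in the repeat. For each list, calls were also counted with p-values adjusted over the list alone.

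Profiles were compared by the root mean square (RMS) log2 difference over all tested genes between each array of a group and each array of another. With 2 arrays against 2 the smallest two-sided p of an exact permutation test is 0.33, so distances carry no p-value. The replicate number was checked as a pairing across groups: residuals of arrays with the same number correlated above 0.1 in 15 of 15 pairs of groups on amplified arrays, with a median of 0.37, and in 3 of 15 on unamplified arrays, with a median of 0.05. On amplified arrays the number coincides with a code in the array names. Fits with the replicate number as a block are therefore given for amplified comparisons where they move a count over all genes by more than 1.5 times. They are also given for part of the lists and named genes whose calls they change.

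The alternatives tried were quantile normalization, centring arrays on their median, a floor at the 25th percentile, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, the replicate number or the array code as a block, variances without a trend and with robust moderation, a fit of only the groups compared, no limit on the size of the change, and leaving out each array in turn. After the data were seen, a floor at the 40th percentile and fits without both amplified EpiSC arrays or both unamplified PGCLC arrays were added. The method was tested on simulated data with 200 changed genes. Of 50 genes changed by a log2 of 2, limma called 47 in the comparison of day 2 EpiLCs with ESCs and 35 in that of PGCLCs with E9.5 PGCs. Of 50 changed by 1.5 it called 42 and 21. Among all unchanged genes there were 2 and 4 false calls. The simulated noise was independent between arrays, unlike that of the amplified arrays, so the count of false calls does not carry over to them. Figures were drawn with matplotlib 3.10.9.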

Results

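The arrays follow mouse pluripotent cells along a route to germ cells, in culture and in the embryo. Unamplified arrays covered 6 groups of 2: embryonic stem cells (ESCs) grown without feeder cells in 2i+LIF, a medium of kinase inhibitors and leukaemia inhibitory factor; epiblast-like cells (EpiLCs) at 1, 2 and 3 days after their induction from ESCs; epiblast stem cells (EpiSCs), which were derived from the epiblast at embryonic day 5.75; and primordial germ cell-like cells (PGCLCs), which were induced from day 2 EpiLCs. Amplified arrays covered another 6 groups of 2: ESCs, day 2 EpiLCs, EpiSCs and PGCLCs again, and 2 cell types from embryos. These were the epiblast at embryonic day 5.5 to 6, before gastrulation, and primordial germ cells (PGCs) at embryonic day 9.5 (E9.5). How PGCs and PGCLCs were isolated, and in which medium EpiSCs were kept, is not given in the sources used here.

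Replicate arrays correlated across genes with r between 0.975, in PGCLCs, and 0.991, in ESCs, on unamplified arrays. On amplified arrays r lay between 0.957 and 0.972, except in EpiSCs, where it was 0.911. The ratio of the 5' to the 3' control probe set of Actb, the gene of beta-actin, was 0.792 to 0.874 on unamplified arrays and 0.0503 to 0.206 on amplified arrays. That of the glycolysis gene Gapdh was 1.13 to 1.21 on unamplified and 0.239 to 0.982 on amplified arrays. Within groups the ratios differed most in the embryo: in the 2 PGC arrays they were 0.0802 and 0.206 for Actb and 0.239 and 0.83 for Gapdh, and in the 2 epiblast arrays 0.0704 and 0.157 for Actb and 0.519 and 0.982 for Gapdh. Differences between cell types were nevertheless similar with and without amplification. Across the 14553 genes tested on both kinds of array, they correlated with r = 0.79 for day 2 EpiLCs minus ESCs, 0.82 for EpiSCs minus day 2 EpiLCs and 0.81 for PGCLCs minus day 2 EpiLCs, and genes are not independent replicates. Of the genes called on amplified arrays, 97.1%, 98.6% and 97.6% had the same sign on unamplified arrays.

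The comparison of day 2 EpiLCs with ESCs asked how the cells change as they leave the ESC state. The transcription factor gene Klf4, a gene of naive pluripotency, the state of the preimplantation epiblast and of ESCs, fell from an intensity of 4870 to 68.6, a log2 difference of -6.15 ± 0.24, and Fgf5, a growth factor gene that marks the epiblast after implantation, rose at least 31.3-fold, from background to 878, with an adjusted p of 7.7e-11. The de novo DNA methyltransferase gene Dnmt3a rose from 50.5 to 3020 and its relative Dnmt3b from 1160 to 9650. The transcripts of Pou5f1, which encodes the pluripotency factor Oct4, had intensities of 6560 in ESCs and 6170 in EpiLCs, a log2 difference of -0.09 ± 0.07 that was not called.

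In all, 2458 genes were called, 1338 higher and 1120 lower in day 2 EpiLCs. Of 16 measured genes of naive pluripotency, 13 fell and 1 rose, Gbx2, which was chosen after its value was seen, and the list shifted down with an adjusted p of 1.29e-40 at the preset correlation but adjusted p = 0.111 with an estimated correlation. Among those that fell were Nr5a2, at least 51.7-fold, Prdm14, at least 19.6-fold, Esrrb, by a log2 of -3.88 ± 0.17, and Nanog, from 5620 to 1270. Of 20 postimplantation genes 14 rose and 1 fell, and 15 rose adjusted over the list alone (adjusted p = 0.122 with an estimated correlation). On amplified arrays both lists passed with either correlation. There 12 of 16 naive genes fell and 0 rose, or 14 fell adjusted over the list alone (adjusted p = 0.0015 with an estimated correlation). Of 20 postimplantation genes 8 rose and 0 fell, or 13 and 1 adjusted over the list alone (adjusted p = 0.00663 with an estimated correlation). The transcription factor gene Pou3f1 rose by 5.84 ± 0.09 and the kinase gene Pim2 by 5.21 ± 0.08, while the activin antagonist gene Fst, chosen after its value was seen, fell by 2.62. Otx2, a regulator of the postimplantation state, had a difference of 1.02 ± 0.40 and was not called, but was called with low values raised to the 40th percentile, an alternative added after the data were seen. The largest changes included a rise of the carbonic anhydrase gene Car4, at least 89.5-fold, and of the lactate transporter gene Slc16a3, at least 24.4-fold, and a fall of the netrin gene Ntn1, at least 39.6-fold.

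Signalling and germ cell lists shifted as well. Of 15 targets of FGF and ERK signalling 7 rose (adjusted p = 0.128 with an estimated correlation). Among them were the phosphatase gene Dusp6, by 4.27 ± 0.08, and Myc, by 2.97 ± 0.29. Fos, chosen after its value was seen, fell by 1.72. On amplified arrays the lowest difference among the 15 was 0.13, so the fall of Fos was not seen again. Of 12 WNT targets 5 fell: Sp5, at least 10.2-fold, Cdx1, Axin2, Notum and, chosen after its value was seen, Rnf43 (adjusted p = 0.265 with an estimated correlation). The 4 of 14 BMP targets that fell were Tbx3, Id4, Gata2 and Id3 (adjusted p = 0.505 with an estimated correlation). Of 19 early germ cell genes, 9 fell, including Tcl1 by 4.98 and the germ cell regulators Tfap2c by 3.10 and Prdm1 by 2.41, while Dnd1, Lin28a and, chosen after its value was seen, Rhox5 rose (adjusted p = 0.279 with an estimated correlation). The call of Dnd1 was lost without ESC replicate 2. Of 19 later germ cell genes, which act in meiosis and transposon silencing, 11 rose, among them Mael by 4.51 ± 0.13 and Ddx4 by 2.11 ± 0.10, and Dazl fell by 1.28 (adjusted p = 0.128 with an estimated correlation). Of 17 fibroblast markers 8 rose, including Dcn, Tagln and Thy1, and 0 fell (adjusted p = 0.122 with an estimated correlation). The hindgut list also shifted (adjusted p = 0.295 with an estimated correlation), and its 4 genes that rose were epithelial: the claudin genes Cldn6 and Cldn7, the adhesion gene Epcam and the keratin gene Krt18, while Krt8, chosen after its value was seen, fell. Adjusted over the list alone, the counts of these lists were the same.

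Day by day, the RMS log2 difference from ESCs was 0.80 at day 1, 0.99 at day 2 and 1.06 at day 3. Between ESCs and day 1, 1797 genes were called, 844 higher and 953 lower; between days 1 and 2, 1201, of which 786 were higher; and between days 2 and 3, 636, of which 221 were higher. From day 1 to day 2, 14 of 16 naive genes fell and 0 rose (adjusted p = 0.061 with an estimated correlation), while of 20 postimplantation genes 0 rose and 1 fell. From day 2 to day 3, 6 of 20 postimplantation genes fell and 0 rose, or 8 fell adjusted over the list alone (adjusted p = 0.244 with an estimated correlation). Day 3 differed from ESCs at 2972 genes, 1483 higher and 1489 lower.

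**Figure D1:**
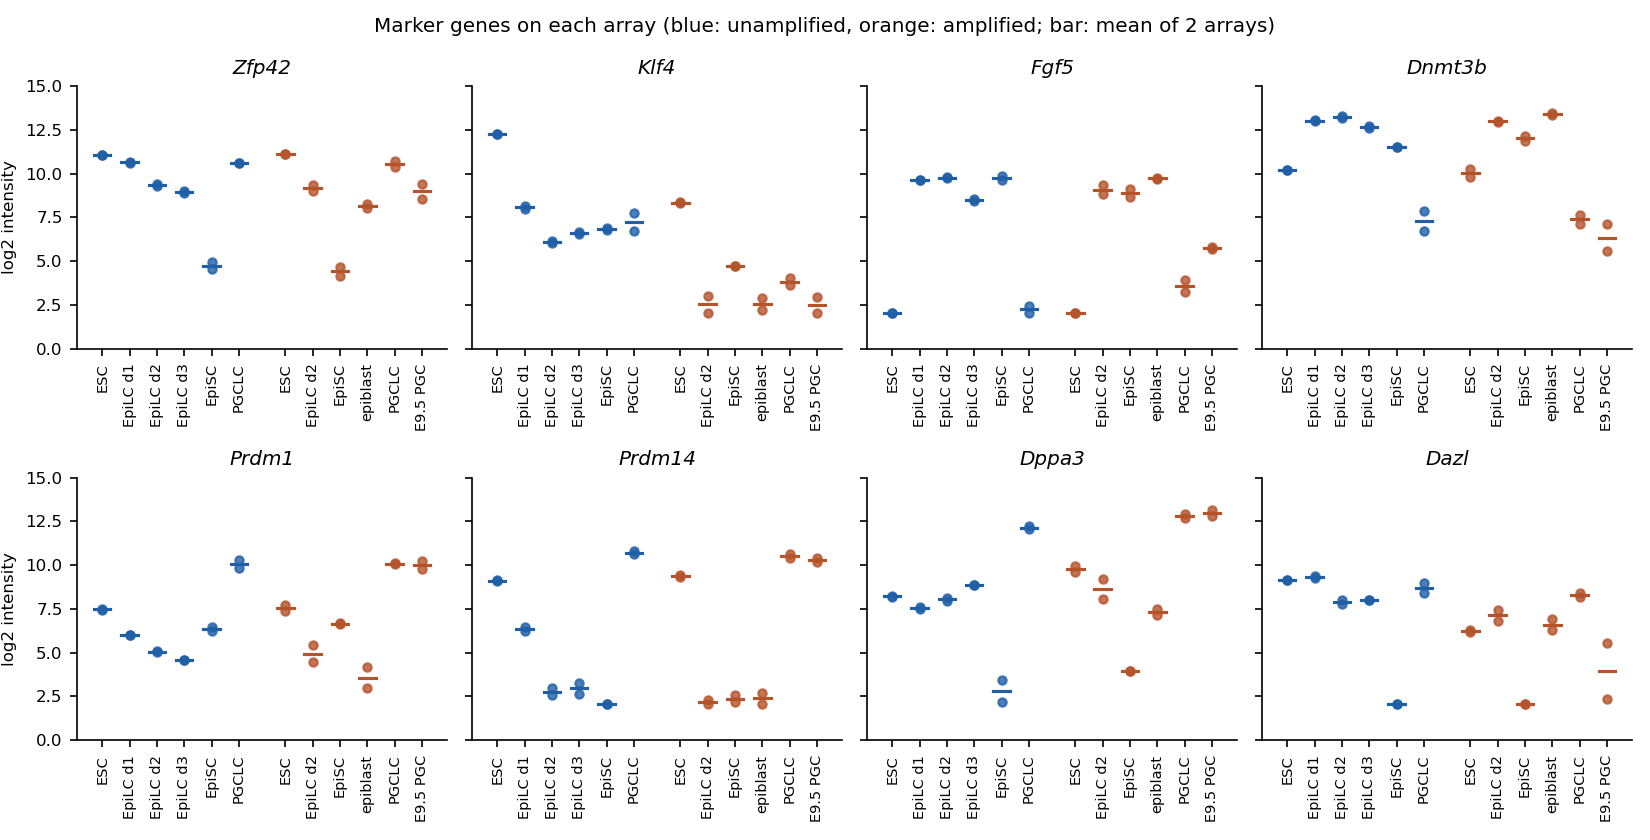
Log2 intensity of 8 marker genes on each array, in blue for unamplified and orange for amplified arrays, with bars at the mean of 2 arrays. Klf4 drops and Fgf5 rises from ESCs to EpiLCs, and Prdm1, Prdm14 and Dppa3 are high in PGCLCs and in E9.5 PGCs.

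The comparison of EpiSCs with day 2 EpiLCs set an established line from the epiblast against the cells induced from ESCs. Fibroblast markers were higher in EpiSCs, 15 of 17 (adjusted p = 0.0179 with an estimated correlation). Later germ cell genes were lower, 16 of 19 (adjusted p = 0.0265 with an estimated correlation). Foxa1 and Foxa2, transcription factor genes of the endoderm, were at least 25.3-fold and at least 25.8-fold higher. Dppa5a, a gene of early embryos and germ cells, fell from an intensity of 11600 to 42.8, and the ribosomal protein gene Rps4l was at least 245-fold lower. Fgf5 differed by -0.02 ± 0.15 and was not called.

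Here 2819 genes were called, 1857 higher and 962 lower in EpiSCs. Of 19 later germ cell genes, 16 fell and 0 rose, with an adjusted p of 3.38e-44 at the preset correlation and adjusted p = 0.0265 with an estimated correlation. Mael was at least 31.3-fold lower and the meiotic gene Hormad1 at least 23.3-fold lower. Of 11 core pluripotency genes, the 4 that fell were Dppa2, at least 63-fold, Dppa4, Utf1 and Dnd1 (adjusted p = 0.135 with an estimated correlation). Of 16 naive genes 7 fell, including Dppa3, at least 9.39-fold, and Zfp42 by 4.59, and Nanog rose by 1.09 ± 0.10 (adjusted p = 0.334 with an estimated correlation), a call lost with arrays centred on their medians, where the difference was 0.86. Of 20 postimplantation genes 9 fell, among them Pou3f1 by 1.42, and 3 rose, Cdh2 by 3.83 ± 0.16, Wnt8a and, chosen after its value was seen, Fst (adjusted p = 0.457 with an estimated correlation). Otx2 fell from 1700 to 602, a call that was lost without day 2 EpiLC replicate 2 or EpiSC replicate 1. Of 10 genes of DNA methylation 4 fell, Dnmt3l, at least 41.6-fold, Dnmt3a, Dnmt3b and the 5-methylcytosine dioxygenase gene Tet1 (adjusted p = 0.457 with an estimated correlation), and with the replicate number as a block the list had an adjusted p of 0.0519. Of 19 early germ cell genes 6 rose, including Tfap2c by 2.21 ± 0.11, and 8 fell (adjusted p = 0.668 with an estimated correlation).

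Of 17 primitive streak and mesendoderm genes, 10 were higher in EpiSCs and 1 lower, Mesp2, which was chosen after its value was seen (adjusted p = 0.334 with an estimated correlation). The signal antagonist gene Cer1 rose at least 17.6-fold and Fgf8 at least 22.8-fold. Imprinted genes rose in 11 of 20 cases, with Igf2 higher by 6.00 ± 0.28 and Plagl1 by 4.48 ± 0.13, and Phlda2, chosen after its value was seen, fell (adjusted p = 0.0555 with an estimated correlation). Of 17 fibroblast markers 15 rose and 0 fell, with an adjusted p of 5e-13 at the preset correlation and adjusted p = 0.0179 with an estimated correlation. On amplified arrays 12 rose and 0 fell, or 15 rose adjusted over the list alone (adjusted p = 0.0511 with an estimated correlation), and 14 of 19 later germ cell genes fell, also adjusted over the list alone (adjusted p = 0.0205 with an estimated correlation). On unamplified arrays the collagen genes Col3a1, at least 44.1-fold, and Col1a2, from 38.3 to 3360, led the fibroblast list, whose median difference was 3.58, and these markers rose in the same EpiSC arrays as the streak and imprinted genes. The 5 of 11 trophoblast markers that rose were the keratin genes Krt19, Krt8, Krt7 and, chosen after its value was seen, Krt18, which are epithelial genes in general, and Plac1 (adjusted p = 0.233 with an estimated correlation). Adjusted over the list alone, the counts of all lists in this comparison were the same. The higher share depended on scaling: centring arrays on their medians gave 1398 higher and 1449 lower and moved the median difference of all genes from 0.02 to -0.208, and quantile normalization gave 1554 higher and 1218 lower, with a median of -0.106.

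Amplified arrays allowed cultured cells to be set beside the embryo, and the first question was which cultured cells come closest to the pregastrulation epiblast. Day 2 EpiLCs did: their RMS log2 difference from the epiblast was 0.74 ± 0.07 (SD over 4 pairs of arrays), against 1.13 ± 0.04 for ESCs, 1.18 ± 0.05 for PGCLCs and 1.19 ± 0.11 for EpiSCs. The 2 epiblast arrays themselves differed by 0.56. The count of called genes was also lowest for day 2 EpiLCs, 150, against 1844 for ESCs and 1823 for EpiSCs.

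**Figure D2:**
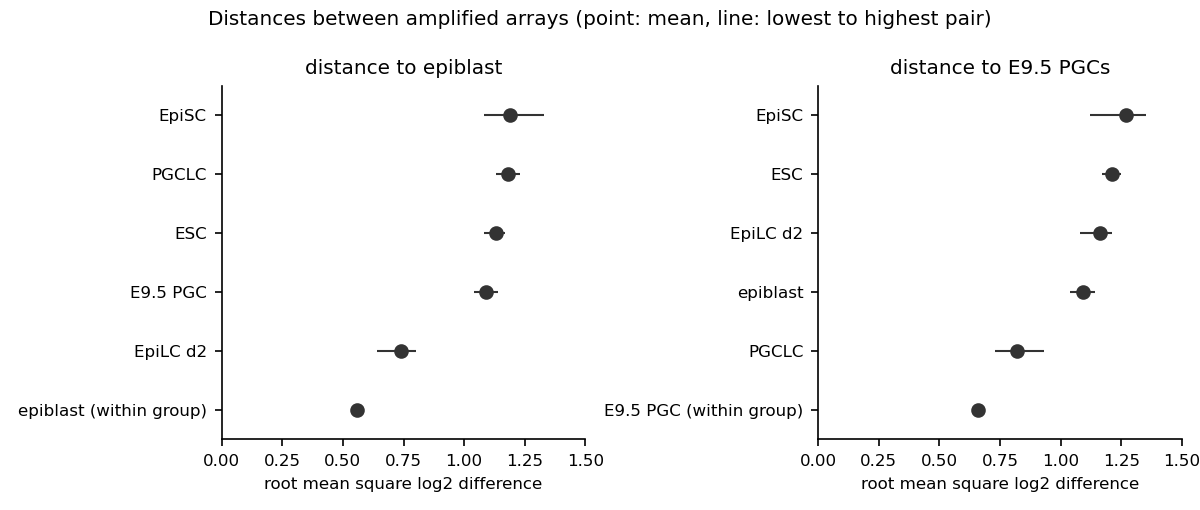
RMS log2 difference over all tested genes between amplified arrays of each group and the epiblast (left) or E9.5 PGCs (right). Points are means over 4 pairs of arrays and lines span the lowest to the highest pair; day 2 EpiLCs lie nearest to the epiblast at 0.74 and PGCLCs nearest to E9.5 PGCs at 0.82.

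Between day 2 EpiLCs and the epiblast, the differences lay in stress genes, in BMP and streak genes and in single genes. The stress regulator gene Nupr1 was at least 61.3-fold higher in EpiLCs (log2 7.12 ± 0.38, adjusted p = 5.3e-05), and Chac1, a target of the stress factor Atf4, was higher by 4.89 ± 0.35. Lefty1, an antagonist of Nodal signalling, was higher by 5.59 ± 0.47. The proteoglycan gene Srgn was at least 13.4-fold lower and Cyp26a1, which encodes an enzyme that degrades retinoic acid, at least 12.6-fold lower. The calls of these 5 genes held when any 1 of the 4 arrays was left out, though that of Lefty1 was lost in a fit of these 2 groups alone. Pou5f1 differed by -0.04 ± 0.26, Fgf5 by -0.64 ± 0.30, Dnmt3b by -0.42 ± 0.43 and Otx2 by -1.54 ± 0.81, and these were not called.

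Of the 150 called genes 102 were higher and 48 lower in EpiLCs. Of 16 stress and apoptosis genes, 6 rose and 0 fell, or 7 rose adjusted over the list alone. The list had an adjusted p of 6.62e-23 at the preset correlation and adjusted p = 0.0237 with an estimated correlation. The factor gene Atf3 was at least 15.6-fold higher. The calls of Trib3 and Ddit3, unlike those of Atf3 and Chac1, were lost when any 1 of the 4 arrays was left out. Of 14 BMP targets 3 were lower, also adjusted over the list alone, namely Id1 by -3.03 ± 0.27, Id3 and Id4 (adjusted p = 0.0237 with an estimated correlation). Of 17 streak genes 5 were lower, or 8 adjusted over the list alone (adjusted p = 0.0492 with an estimated correlation). They were Lhx1, Eomes, Evx1, Gsc and, chosen after its value was seen, Foxa2. The calls of Eomes, Evx1, Gsc and Id4 were lost when any 1 of the 4 arrays was left out, that of Lhx1 without EpiLC replicate 2 or either epiblast array, and that of Id3 without either epiblast array. With low values raised to the 40th percentile Lhx1, Gsc and Id4 were not called, nor was Id4 with the mean of its probe sets. Of 13 visceral endoderm markers 3 were lower, the apolipoprotein gene Apoa1, Cubn and Dab2, and adjusted over the list alone 6 were lower and 1 higher (adjusted p = 0.118 with an estimated correlation). The call of Apoa1 was lost without EpiLC replicate 2 and with low values raised to the 40th percentile, that of Cubn without either EpiLC array or epiblast replicate 1, and that of Dab2 when any 1 of the 4 arrays was left out and with the mean of its probe sets. These visceral endoderm transcripts were lower together with those of the streak and BMP lists.

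Smaller shifts also passed the test of lists. The postimplantation list had 0 called of 20, with a median of -0.47 (adjusted p = 0.0648 with an estimated correlation), and the naive list had 0 called of 16, or 4 higher adjusted over the list alone, with a median of 0.59 (adjusted p = 0.118 with an estimated correlation) that was 0.09 with low values raised to the 40th percentile. The count of 150 depended on single arrays: it was 69 without EpiLC replicate 1, 35 without EpiLC replicate 2, 23 without epiblast replicate 1 and 33 without epiblast replicate 2, and 11 in a fit of these 2 groups alone. With the replicate number as a block 309 genes were called, 218 higher and 91 lower, and without both EpiSC arrays, an alternative added after the data were seen, 266.

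EpiSCs, derived from the epiblast, were compared with it to see what the line had gained and lost. Again fibroblast markers were higher, 13 of 17 (adjusted p = 0.0322 with an estimated correlation). Later germ cell genes were again lower, 13 of 19 (adjusted p = 0.0297 with an estimated correlation). Foxa1 was at least 33.9-fold higher and Col3a1 at least 42.7-fold higher, and the immediate early gene Fos was higher by 6.78 ± 0.32. Dppa2 was at least 31.1-fold lower, Dnmt3l at least 29.8-fold lower and Rps4l at least 229-fold lower. Pou5f1 differed by -0.23 ± 0.26 and Fgf5 by -0.85 ± 0.30, and neither was called.

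Of 1823 called genes 1400 were higher and 423 lower in EpiSCs. Of 19 later germ cell genes 13 fell and 0 rose, or 1 rose adjusted over the list alone, with adjusted p = 0.0297 with an estimated correlation; the meiotic gene Sycp3 was at least 16.1-fold lower and Mael at least 10-fold lower. Of 17 fibroblast markers 13 rose, or 14 adjusted over the list alone (adjusted p = 0.0322 with an estimated correlation), in the same arrays as the other genes that rose. Core pluripotency genes were lower in 4 of 11 cases, Dppa2, Dppa4, Utf1, not called without either epiblast array, and Dnd1, and higher in 1, Sox2, whose call was lost without EpiSC replicate 2 or either epiblast array and with quantile normalization, or lower in 5 adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation). Postimplantation genes were lower in 6 of 20 and higher in 2, Wnt8a and, chosen after its value was seen, Fst, or lower in 8 adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation). Of 18 imprinted genes 7 rose, also adjusted over the list alone, among them Plagl1 by 5.83 ± 0.54 and Igf2 by 3.19 ± 0.39 (adjusted p = 0.195 with an estimated correlation). Of 17 streak genes 5 rose and 1 fell, Evx1, chosen after its value was seen, or 6 and 2 adjusted over the list alone (adjusted p = 0.787 with an estimated correlation). Of 13 visceral endoderm markers 4 were lower and 2 higher, or 6 and 2 adjusted over the list alone (adjusted p = 0.423 with an estimated correlation). In ESCs minus the epiblast 6 of these 13 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). Dnmt3a fell by 2.84 ± 0.30, while Dnmt3b had a difference of -1.38 ± 0.43 that was not called, with an adjusted p of 0.066, but was called with the replicate number as a block, with an adjusted p of 0.028. The lists of nodal targets and hindgut markers passed the test but not with the block, where their adjusted p-values were 0.107 and 0.0977 (adjusted p = 0.923 with an estimated correlation for both).

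The count in EpiSCs changed with the arrays and the scaling used: it was 3444 without EpiSC replicate 1, 889 without epiblast replicate 1, 845 without epiblast replicate 2, and 459 in a fit of these 2 groups alone. Quantile normalization gave 1141 higher and 571 lower, and centring arrays on their medians gave 1003 higher and 706 lower and moved the median difference of all genes to -0.187. ESCs differed from the epiblast at 1844 genes, 1036 higher and 808 lower, with 16 of 16 naive genes higher (adjusted p = 0.00131 with an estimated correlation) and 12 of 20 postimplantation genes lower, or 13 adjusted over the list alone. That count was 1037 and 1083 without ESC replicate 1 and 2, and 1068 and 1035 without epiblast replicate 1 and 2.

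PGCLCs were compared with day 2 EpiLCs, the cells from which they were induced, to follow the induction of the germ cell programme in culture. Prdm14, a regulator of PGC specification, rose at least 59.7-fold, to an intensity of 1680, Prdm1, which encodes the repressor Blimp1, from 33.5 to 1070, and Tfap2c from 158 to 4640. Dppa3, a maternal factor gene expressed in PGCs, rose from 264 to 4510, and Kit, the receptor gene for stem cell factor, from 127 to 1920. Fgf5 was at least 31.3-fold lower and Dnmt3b fell from 9650 to 158.

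In all 3082 genes were called, 1311 higher and 1771 lower in PGCLCs. Of 19 early germ cell genes 15 rose and 2 fell, Lin28a by 1.53 ± 0.08 and, chosen after its value was seen, Cbx7, with an adjusted p of 2.83e-35 at the preset correlation but adjusted p = 0.110 with an estimated correlation. Of 16 naive genes 13 rose, including Nr5a2, at least 20.4-fold, Tcl1 by 4.44 ± 0.12, Esrrb by 3.12 ± 0.17, Nanog by 1.44 ± 0.10 and Zfp42 by 1.28 ± 0.11, while Fgf4 fell by 5.36 ± 0.33, as did, chosen after its value was seen, Gbx2 (adjusted p = 0.110 with an estimated correlation). Klf4 rose by 1.13 ± 0.24, a call lost without PGCLC replicate 1, where the difference was 0.63, and in a fit of these 2 groups alone. Of 20 postimplantation genes 14 fell, including Pou3f1 by 6.00 ± 0.09 and Otx2 by 5.79 ± 0.40, and Cdh2, chosen after its value was seen, rose (adjusted p = 0.110 with an estimated correlation). Pou5f1 differed by 0.05 ± 0.07 and was not called, and Sox2 rose by 1.37 ± 0.04. On amplified arrays these lists passed with either correlation. There 16 of 19 early germ cell genes rose and 1 fell, or 16 and 2 adjusted over the list alone (adjusted p = 0.0118 with an estimated correlation). Of 16 naive genes 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, and of 20 postimplantation genes 13 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00562 with an estimated correlation for both).

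The 4 of 10 DNA methylation genes that fell were those of the de novo enzymes, Dnmt3b, Dnmt3a and their cofactor Dnmt3l, and Uhrf1, whose product directs maintenance methylation, which fell by 1.96 ± 0.11. The list passed the test with an adjusted p of 0.0254 (adjusted p = 0.731 with an estimated correlation), and with the replicate number as a block the adjusted p was 0.0755. Of 20 genes of repressive histone marks 3 fell, the heterochromatin protein gene Cbx3 by 2.39, the demethylase gene Kdm4c by 1.26 and the methyltransferase gene Ehmt1 by 1.18 ± 0.09, and 1 rose, the demethylase gene Kdm3a. The list did not pass the test. On amplified arrays 0 of the 20 were called, or 1 higher with the replicate number as a block. The lowest difference there was -0.87, so these falls were not seen again. Of 12 genes of base excision repair, the 2 that rose were the uracil glycosylase genes Ung and Smug1, chosen after their values were seen (adjusted p = 0.110 with an estimated correlation). Of 14 BMP targets 8 rose and 0 fell, among them Gata2, at least 28.4-fold, Msx2 by 4.34 ± 0.30 and Id3 by 3.33 ± 0.15 (adjusted p = 0.110 with an estimated correlation). On amplified arrays 6 BMP targets rose and 0 fell, or 7 rose adjusted over the list alone (adjusted p = 0.0172 with an estimated correlation). Imprinted genes went both ways, 8 of 20 up, including Plagl1 by 5.80 ± 0.13, and 3 down, Grb10 by 4.11 ± 0.17 and, chosen after their values were seen, Phlda2 and Mirg (adjusted p = 0.731 with an estimated correlation). Of 15 hindgut markers, the intestinal regulator gene Cdx2 rose at least 13.6-fold, while the epithelial genes Cdh1, Cldn6 and Krt18 and, chosen after its value was seen, the hormone gene Pyy fell (adjusted p = 0.388 with an estimated correlation). Later germ cell genes did not shift as a list: 2 of 19 rose and 5 fell, among them Sycp3 by 2.94 ± 0.11, and Ddx4 differed by 0.14 ± 0.10 and Dazl by 0.78 ± 0.16 without being called. The list did not pass on amplified arrays either, but its counts there went the other way, with 4 higher and 1 lower, or 5 and 2 adjusted over the list alone, and a median of 0.37 against -0.22. Adjusted over the list alone, the counts of the lists in this comparison were the same, except that 7 fibroblast markers rose in place of 6 of 17. Against ESCs, PGCLCs differed at 3080 genes, 1405 higher and 1675 lower, and 13 of 19 early germ cell genes were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.193 with an estimated correlation).

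**Figure D3:**
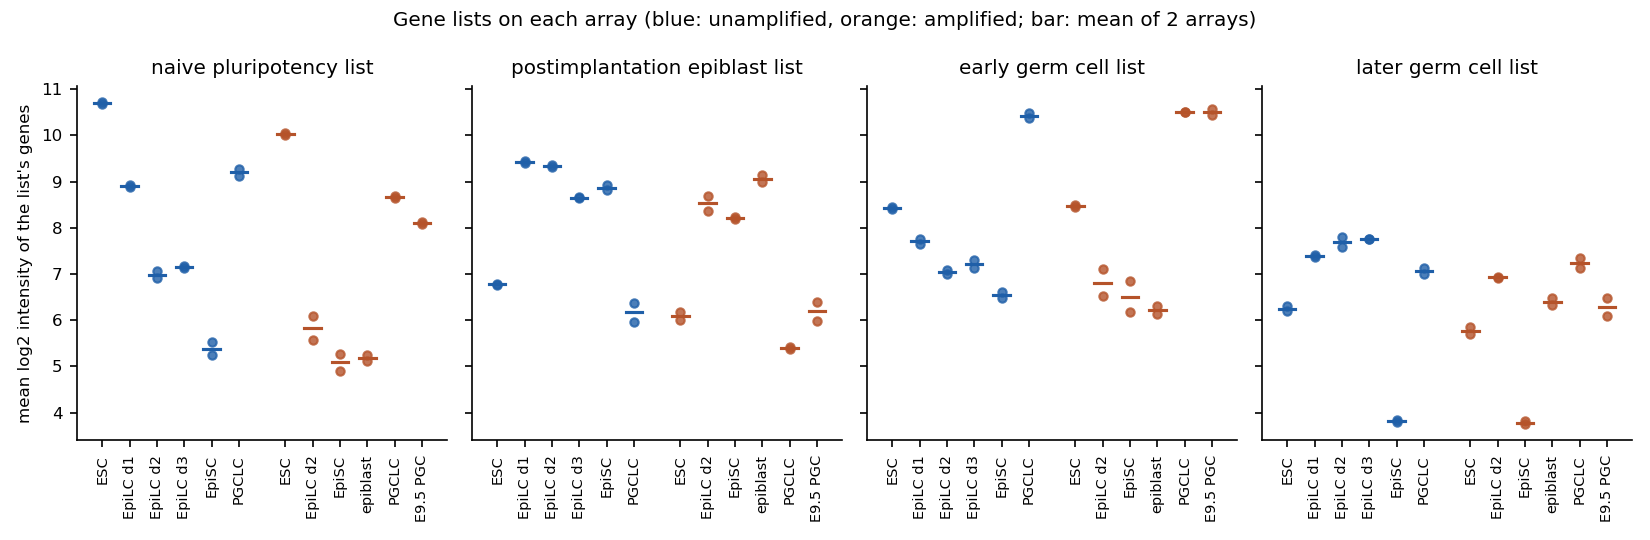
Mean log2 intensity of the measured genes of 4 lists on each array, in blue for unamplified and orange for amplified arrays, with bars at the mean of 2 arrays. Early germ cell genes are highest in PGCLCs and E9.5 PGCs, and later germ cell genes are lowest in EpiSCs.

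The matching step in the embryo runs from the epiblast to E9.5 PGCs. Here too Prdm14 was at least 51.6-fold higher, Prdm1 at least 42.7-fold higher, and Dppa3 rose from 160 to 8050. Dnmt3b fell from 10800 to 81.3, Otx2 was at least 41.5-fold lower, and Eras, a Ras-like gene of pluripotent cells, at least 49.6-fold lower. Hoxb9, a posterior Hox gene, was at least 8.22-fold higher, and the embryonic globin gene Hba-x rose from 29.2 to 5260. The intensities of Pou5f1 differed by a log2 of -0.09 ± 0.26, which was not called.

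Of 1635 called genes 954 were higher and 681 lower in PGCs. Of 19 early germ cell genes 15 rose and 0 fell, also adjusted over the list alone, with an adjusted p of 8.99e-57 at the preset correlation and adjusted p = 0.00571 with an estimated correlation. Kit rose by 4.59 ± 0.39, Tfap2c by 4.34 ± 0.55 and Rhox9, a homeobox gene on the X chromosome, at least 155-fold. Of 16 naive genes 11 rose, among them Klf2, at least 48.1-fold, and Nr5a2, at least 15-fold, and Fgf4 was at least 22.6-fold lower (adjusted p = 0.00549 with an estimated correlation). Nanog rose by 1.69 ± 0.35, a call lost when any 1 of the 4 arrays was left out. Of 20 postimplantation genes 14 fell and 0 rose (adjusted p = 0.00549 with an estimated correlation). Adjusted over the list alone, the counts of both lists were the same. DNA methylation genes fell in 3 of 10 cases, Dnmt3b by 7.05 ± 0.43, Dnmt3l, at least 29.8-fold, and Dnmt3a by 3.73 ± 0.30, and the methyl-CpG binding protein gene Mbd2 rose, a call lost without either epiblast array or PGC replicate 1; adjusted over the list alone 4 fell and 2 rose (adjusted p = 0.361 with an estimated correlation). BMP targets rose in 4 of 14 cases, or 5 adjusted over the list alone, including Gata2 by 4.11 ± 0.43 and Msx2 by 3.48 ± 0.29 (adjusted p = 0.0721 with an estimated correlation).

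Of 18 Hox genes 6 rose, or 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.286 with an estimated correlation), and Hoxb9, Hoxb1 and Hoxc8 were among them, the last not called with low values raised to the 40th percentile. In the same PGC arrays, the endothelial and blood markers Hba-x and Hbb-bh1, both globin genes, rose, while the list as a whole, with 4 of 13 higher and 1 lower, did not pass the test. The 1 that was lower was the globin gene Hbb-y, by 3.08 ± 0.27. Its probe set, that with the highest mean over all 24 arrays, lay at the floor of 2.07 in both PGC arrays, while 2 other Hbb-y probe sets lay between 12.25 and 13.3 there and at most at 2.17 in epiblast and PGCLC arrays. The mean over the probe sets of Hbb-y rose by 6.11. Streak genes fell in 4 of 17 cases, with Eomes lower by -4.78 ± 0.42 (adjusted p = 0.361 with an estimated correlation). Of 17 glycolysis genes 3 fell, including Tpi1 by 1.38 ± 0.19. Adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.127 with an estimated correlation). In PGCLCs minus day 2 EpiLCs the glycolysis list differed between amplified and unamplified arrays, as given below. With the replicate number as a block, the lists of streak, visceral endoderm and trophoblast genes did not pass, with adjusted p-values of 0.0554, 0.0633 and 0.0554, and Dazl, with a difference of -2.64 ± 0.79 and an adjusted p of 0.062, was called lower, with an adjusted p of 0.026, as it was without PGC replicate 1. The count of 1635 was 821 without epiblast replicate 1, 794 without epiblast replicate 2, 972 without PGC replicate 2, and 1108 without PGC replicate 1, with 527 higher and 581 lower.

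PGCLCs were then compared with E9.5 PGCs directly, their counterpart in the embryo according to the series description. Their RMS log2 difference was 0.82 ± 0.09 (SD over 4 pairs of arrays), against 1.09 ± 0.05 between the epiblast and E9.5 PGCs, 1.16 ± 0.05 for day 2 EpiLCs, 1.21 ± 0.04 for ESCs and 1.27 ± 0.11 for EpiSCs, and the 2 PGC arrays differed by 0.66. Of 19 early germ cell genes 0 were called, also adjusted over the list alone, while with the replicate number as a block 1 was lower in PGCLCs. The differences of Prdm1, Prdm14, Tfap2c, Dppa3 and Kit were 0.07 ± 0.43, 0.23 ± 0.28, -0.26 ± 0.55, -0.19 ± 0.36 and -0.29 ± 0.39. Over the list they ranged from -1.89 to 1.29. Changes of this size can be missed, since simulated changes by a log2 of 1.5 were called in 21 of 50 genes. Among the called genes, Hoxb9 and Ldha were lower in PGCLCs, and Lefty1, Lefty2 and Ccng1 higher.

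Of 452 called genes 244 were higher and 208 lower in PGCLCs. Of 18 Hox genes 3 were lower, Hoxb9, at least 8.22-fold, Hoxb1 and Hoxc8. Adjusted over the list alone 8 were lower (adjusted p = 0.0792 with an estimated correlation), and with the replicate number as a block 6. The calls of Hoxb1 and Hoxc8 were lost without either PGCLC array or PGC replicate 1, as were those of 2 of the 3 neural genes that were lower of 14, Zic1 and Neurog2. With low values raised to the 40th percentile Hoxc8 and all 3 neural genes, Zic1, Neurog2 and Sox1, were not called, nor was Sox1 with the mean of its probe sets. In all, 5 neural genes were lower adjusted over the list alone (adjusted p = 0.167 with an estimated correlation), and 5 with the replicate number as a block. The somite gene Meox1 was at least 8.31-fold lower and the cartilage collagen gene Col2a1 at least 8.39-fold lower in PGCLCs, and Hba-x at least 219-fold lower. Of 17 fibroblast markers 3 were lower in the same comparison, or 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.257 with an estimated correlation). Of 17 glycolysis genes 4 were lower, among them the lactate dehydrogenase gene Ldha, at 407 against 6050, and Tpi1 by -1.40 ± 0.19. Adjusted over the list alone 1 was also higher (adjusted p = 0.0996 with an estimated correlation). In PGCLCs minus day 2 EpiLCs this list depended on amplification. On amplified arrays 2 rose and 6 fell there, with a lowest difference of -7.76 (adjusted p = 0.152 with an estimated correlation). On unamplified arrays 3 rose and 1 fell, with a lowest difference of -1.99, and the list did not pass. PGCs were measured on amplified arrays only. BMP targets were lower in 3 of 14 cases, or 4 adjusted over the list alone, with Id4 at -2.91 ± 0.27 and Id1 at -2.53 ± 0.27 (adjusted p = 0.117 with an estimated correlation). Of 20 postimplantation genes 3 were lower, Fst, Sox3 and Fgf5, and 1 higher, Grhl2. Adjusted over the list alone 5 were lower and 1 higher (adjusted p = 0.0792 with an estimated correlation). With low values raised to the 40th percentile Fst, Sox3 and Fgf5 were not called, nor were Fst, Sox3 and Grhl2 with the mean of their probe sets. The naive gene Zfp42 was higher by 1.57 ± 0.33, and by 1.13 to 2 with single arrays left out.

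Higher in PGCLCs were Lefty2 by 3.76 ± 0.36 and Lefty1 by 3.62 ± 0.47, 2 of 3 nodal targets called of 10, also adjusted over the list alone (adjusted p = 0.257 with an estimated correlation). The later germ cell genes Dazl, by 4.33 ± 0.79, and, chosen after its value was seen, Mael were higher, 2 of 19. Adjusted over the list alone 6 were higher (adjusted p = 0.0792 with an estimated correlation), and with the replicate number as a block 4. The call of Dazl was lost without either PGCLC array. In PGCs Dazl had a log2 mean of 3.97 with an SD of 2.26 over the 2 arrays. Its difference ran from 2.73 to 5.93 with single arrays left out. Of 16 stress genes 3 were higher, or 5 adjusted over the list alone and 7 with the replicate number as a block (adjusted p = 0.0849 with an estimated correlation). The p53 target gene Ccng1 was higher by 2.48 ± 0.28. Of 13 endothelial and blood markers 6 were higher and 2 lower in PGCLCs, or 7 and 2 adjusted over the list alone (adjusted p = 0.162 with an estimated correlation). The endothelial sialomucin gene Emcn was higher by 2.99, a call lost without either PGCLC array, and the 2 that were lower were the globin genes Hba-x and Hbb-bh1, the second of which was not called without either PGCLC array or PGC replicate 1. One of the 6 that were higher was Hbb-y, by 3.22, with the same probe set at the floor in PGCs, and it had a difference of -6.04 by the mean of its probe sets. Fabp3, a gene of fatty acid transport, was higher by 5.61 ± 0.46, and Bcl3 at least 10.4-fold higher.

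The count of 452 depended on single arrays, with 91 and 109 without PGCLC replicate 1 and 2 and 190 and 284 without PGC replicate 1 and 2, and in a limma fit of these 2 groups alone it was 0, with 2032 genes at an unadjusted p under 0.05. It was 774 with the replicate number as a block, 400 higher and 374 lower, and 692 without both EpiSC arrays, an alternative added after the data were seen.

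Finally, the step from day 2 EpiLCs to PGCLCs in culture was set against the step from the epiblast to PGCs in the embryo, on amplified arrays with no array in common. Across genes the differences of both steps correlated with r = 0.70, a correlation over genes that are not independent replicates, and single replicates gave r between 0.60 and 0.68. Both steps called 985 genes: 546 higher in both, 427 lower in both and 12 in opposite directions. If calls in the 2 steps were independent across genes, 61.7 and 42.5 would be shared. Both steps use the same variance of each gene, so calls are not independent and these expected counts are only a rough guide. With the replicate number as a block both steps called 1347 genes: 713 higher in both, 607 lower in both and 27 in opposite directions. The counts expected from independent calls were then 106 and 79.6. The change of Prdm14 differed between the steps by 0.43 ± 0.39, that of Dppa3 by -1.49 ± 0.51 and that of Prdm1 by -1.30 ± 0.60, and none of the 3 was called.

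**Figure D4:**
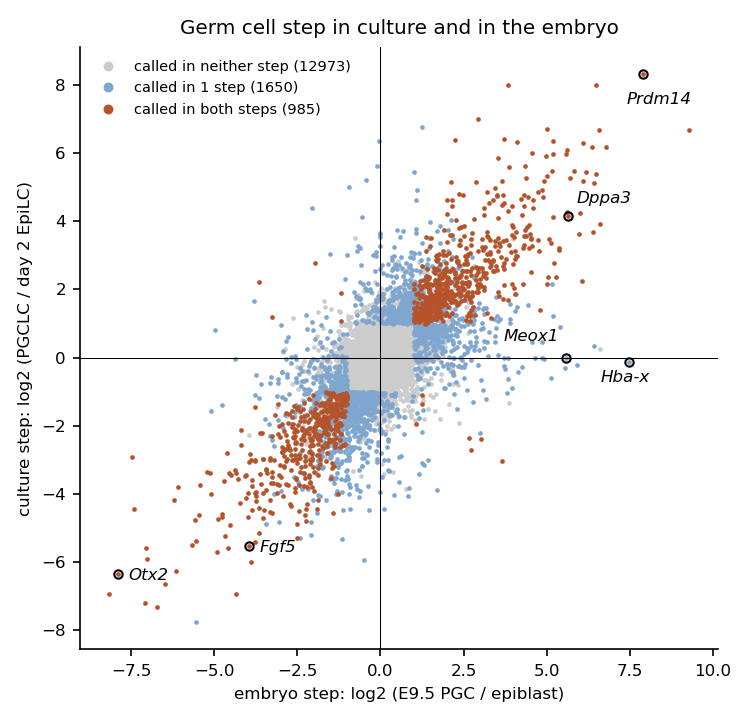
Log2 difference of each gene in the embryo step, E9.5 PGC over epiblast (horizontal), and in the culture step, PGCLC over day 2 EpiLC (vertical), on amplified arrays. Of all genes, 985 are called in both steps (red), mostly near the diagonal, 1650 in 1 step (blue) and 12973 in neither (grey) while Hba-x and Meox1 lie far to the right near the horizontal axis.

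A test of the difference between the steps called 80 genes, 30 with a more positive and 50 with a more negative change in culture. Srgn, with a difference of 6.39 ± 0.47, Fabp3, 5.87 ± 0.64, the streak gene Lhx1, 5.74 ± 0.58, and the glutaredoxin gene Glrx, 5.65 ± 0.56, had a more positive change in culture, and the neural gene Sox1, at -5.40 ± 0.54, a more negative one. In Srgn, Glrx and Lhx1 the starting cells differed: log2 means were 2.07, 4.90 and 2.07 in day 2 EpiLCs and 8.33, 9.48 and 5.53 in the epiblast, against 8.42, 10.12 and 7.70 in PGCLCs and 8.29, 9.06 and 5.42 in PGCs. Fabp3 had 8.08 in EpiLCs, 8.34 in the epiblast, 10.30 in PGCLCs and 4.69 in PGCs, and Sox1 had 4.45, 2.07, 2.07 and 5.09. The 5 calls held when any 1 of the 8 arrays was left out, but with low values raised to the 40th percentile Lhx1, at 3.11, and Sox1, at -0.46, were not called, nor was Sox1 with the mean of its probe sets. Of 17 streak genes 2, Lhx1 and, chosen after its value was seen, Eomes, had a more positive change in culture, or 4 adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). Hox genes had a more negative change in culture in 1 of 18 cases, Hoxb9, chosen after its value was seen, or 6 adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). Neural genes did in 1 of 14, Sox1, or 3 adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). The lists of early germ cell, later germ cell and visceral endoderm genes passed the test but had 0 called members each, and not with the block, where their adjusted p-values were 0.0646, 0.120 and 0.0646. With an estimated correlation, adjusted p = 0.346, 0.299 and 0.48.

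The count of 80 was 18 and 34 without EpiLC replicate 1 and 2, 14 and 12 without epiblast replicate 1 and 2, 14 and 12 without PGCLC replicate 1 and 2 and 32 without PGC replicate 1. It was 257 with the replicate number as a block, 110 higher and 147 lower, and 177 without both EpiSC arrays, an alternative added after the data were seen.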

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

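Of the tests below, those of single EpiSC arrays, of globin probe sets, of trunk mesoderm genes, of immediate early genes, of Atf4 targets and of the epiblast arrays were chosen only after the result was seen.

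Fibroblast genes were higher in EpiSCs than in day 2 EpiLCs, with 15 of 17 markers called, Col1a2 rising from 38.3 to 3360. A single unusual array is argued against, since the median of the list above the EpiLC mean was 3.58 and 3.57 in the unamplified and 3.36 and 2.55 in the amplified EpiSC arrays. RNA of feeder fibroblasts or of fibroblast-like cells in the EpiSC cultures is a candidate explanation: of 22 measured genes of a further list, 0 of them in any other list, 14 were called higher (63.6%, against 12.4% of all genes), among them Twist2, Pdgfrb and Bgn, chosen after their values were seen. The sources used here name neither feeder cells nor a sort for EpiSCs, and 14 of the 22 genes also lay above the filter in both day 2 EpiLC arrays. Expression of these genes by the EpiSCs themselves, a difference between cell types that the design names, would give the same values. The further list therefore cannot tell the source, and this explanation stays open and was not tested. Against ESCs grown without feeder cells, 8 of the 17 markers were higher in day 2 EpiLCs and 10 in PGCLCs on unamplified arrays. In both 0 were lower (adjusted p = 0.122 and 0.106 with an estimated correlation).

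The globin genes Hba-x, at 5260 in PGCs, and Hbb-bh1 were higher in E9.5 PGCs than in PGCLCs, as were 3 of 18 Hox genes (adjusted p = 0.0792 with an estimated correlation). Of 14 detected globin probe sets, 9 lay at least 2 log2 units higher in both PGC arrays than in every epiblast and PGCLC array. These include the probe sets of Hba-x and Hbb-bh1 themselves, the genes that prompted the test. Globin transcripts made by the PGCs would give the same values, so the test cannot tell their source. RNA of red blood cells is a candidate explanation for the globins that it does not decide. Of 18 other red cell genes 1, Hemgn, was called higher in PGCs and 1, Fech, lower, both chosen after their values were seen. The median difference, PGCLCs minus PGCs, was -0.17. This argues only weakly against whole red cells in number. The reason is that 14 of the 18 genes also lay above the filter in both PGCLC arrays, where added RNA would raise them less. A small share of cells or free globin RNA stays open. Of 18 trunk mesoderm genes apart from Meox1, one of the largest differences, with 1 of the 18 in another list, 4 were called higher in PGCs (22.2%, against 1.33% of all genes), Foxc1, Foxc2, Pdgfra and Dll1, chosen after their values were seen, which does not exclude cells of the trunk but is below the share of 1 in 3 set for them. For the Hox genes, RNA of such cells and expression by the PGCs themselves cannot be told apart, since no purity of the PGC samples is given.

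Stress genes were higher in day 2 EpiLCs than in the epiblast, with 6 of 16 called. Among these, the calls of Trib3 and Ddit3 were lost when any 1 of the 4 arrays was left out. The epiblast arrays alone stay open as the source. Against them the list had 8 genes higher and 0 lower in ESCs, with a median of 1.13 (adjusted p = 0.0897 with an estimated correlation). In EpiSCs it had 5 and 0, with a median of 0.92 (adjusted p = 0.177 with an estimated correlation). PGCLCs minus E9.5 PGCs, which uses no epiblast array, had a median of 0.89 (adjusted p = 0.0849 with an estimated correlation). There 3 genes were called higher, of which 1, Chac1, is called here, or 7 with the replicate number as a block. Dissociation of the cultured cells could raise immediate early genes: apart from Egr1, one of the largest increases, 2 of 11 were called higher (18.2%, against 0.654% of all genes), Fos and Jun, chosen after their values were seen, or 4 with the replicate number as a block, and 2 of the 11 are in another list. An amino acid response in culture could raise targets of Atf4: apart from Nupr1, the largest increase, 2 of 19 in a further list were called higher (10.5%, against 0.654%), Slc3a2 and Gpt2, chosen after their values were seen, or 9 with the block. These cannot be told apart: without the block both lists fall between the shares that would argue for and against them, and with it both pass the share that would argue for them.

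The change from day 2 EpiLCs to PGCLCs differed from that from the epiblast to PGCs, by the test of the difference, at 80 genes. The culture step had a more positive change for Srgn, by 6.39, Fabp3, by 5.87, Lhx1, by 5.74, and Glrx, by 5.65, and a more negative one for Sox1, at -5.40, all called without any 1 of the 8 arrays. Tinagl1, at 6.46, lost its call without any 1 of the 8 arrays, and Lcp1, at 5.53, without epiblast replicate 1 or either PGCLC array. More negative in the culture step were also Hba-x, at -7.61, Pcdh8, at -6.68, Aldh1a2, at -5.84, and Meox1, at -5.57, which were called only without PGC replicate 2 when 1 array was left out, and Igfbp5, at -5.46, only without either PGC array. With the floor at the 40th percentile Lhx1, Sox1, Pcdh8, Aldh1a2 and Meox1 were not called, at the 25th Sox1, Pcdh8 and Meox1, and with the mean of probe sets Sox1, Tinagl1 and Pcdh8. Without the filter on dim probe sets Tinagl1, Hba-x, Pcdh8, Aldh1a2, Meox1 and Igfbp5 were not called. The count of 80 without single arrays lay between 12 and 91. Amplified and unamplified arrays differed in the change from ESCs to day 2 EpiLCs at 124 genes, 56 higher and 68 lower on amplified arrays, and without single arrays at 34 to 169. For the change from day 2 EpiLCs to PGCLCs they differed at 123, 77 higher and 46 lower, and without single arrays at 40 to 280; centring arrays on their medians gave 66 higher and 65 lower.

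Probe sets without a listed gene, which the comparisons of genes do not use, also carried signal. Of 9160 such probe sets that are not controls, 4401 were tested for PGCLCs minus day 2 EpiLCs on unamplified arrays, and 711 were called, 321 higher and 390 lower. For E9.5 PGCs minus the epiblast 4539 were tested and 92 called, 39 higher and 53 lower.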

How the results depend on the processing

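Of the settings below, the floor at the 40th percentile and the fits without both amplified EpiSC or both unamplified PGCLC arrays were chosen only after the data were seen. Over all settings, 284 counts and distances stayed within 1.5 times, or within 1 SD, of the values reported and 91 did not; of list medians 697 kept their direction and their side of the threshold, 119 lost and 14 gained a call and 2 reversed, and of named genes 8356 kept both, 514 lost and 23 gained a call and 4 reversed. Calls are limited by 2 arrays per group and, for dim genes, by signal near background. Where nothing else is said, the cause was not tested.

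Without a limit on the size of the change, which adds genes by construction, the unamplified counts became 5958 (day 1 EpiLC minus ESC), 6864 (day 2 minus ESC), 7717 (day 3 minus ESC), 4830 (day 2 minus day 1), 3844 (day 3 minus day 2), 7816 (EpiSC minus day 2 EpiLC), 8209 (PGCLC minus day 2 EpiLC) and 8167 (PGCLC minus ESC). In the same order, leaving out single arrays, with the lone array assumed to vary like the other groups, gave 1715 to 1771, 2390 to 2414, 2867 to 3050, 1033 to 1146, 543 to 707, 2625 to 2799, 2948 to 3366 and 3014 to 3538. On amplified arrays it gave 1035 to 1083 (ESC minus epiblast), 23 to 69 (day 2 EpiLC minus epiblast), 845 to 3444 (EpiSC minus epiblast), 659 to 911 (day 2 EpiLC minus ESC), 1148 to 3956 (EpiSC minus day 2 EpiLC), 1013 to 1332 (PGCLC minus day 2 EpiLC), 794 to 1108 (PGC minus epiblast), 91 to 284 (PGCLC minus PGC) and 12 to 91 (culture minus embryo step). For the effect of amplification it gave 34 to 169 (day 2 EpiLC minus ESC) and 40 to 280 (PGCLC minus day 2 EpiLC).

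With the replicate number as a block the counts were 309 (day 2 EpiLC minus epiblast), 774 (PGCLC minus PGC), 257 (culture minus embryo step) and 342 and 385 (amplification), and with the array code 284 for the first of the last pair. Without both EpiSC arrays they were 266, 692 and 177 for the first 3 of these. In fits of only the groups compared, with fewer arrays to estimate the variance, they were 11 (day 2 EpiLC minus epiblast), 459 (EpiSC minus epiblast), 464 (EpiSC minus day 2 EpiLC, amplified), 0 by limma for PGCLC minus PGC, with 2032 at an unadjusted p under 0.05, and 14 (amplification, PGCLC minus day 2 EpiLC). The floor at the 40th percentile gave 137 for culture minus embryo step and 274 and 270 for amplification, and the floor at the 25th percentile 187 for the second of these.

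With an estimated correlation between genes, 0 lists in place of 10 were called for day 2 EpiLC minus ESC, 2 in place of 10 for EpiSC minus day 2 EpiLC, 0 in place of 8 for PGCLC minus day 2 EpiLC, 3 in place of 15 for day 2 EpiLC minus epiblast, 4 in place of 13 for EpiSC minus epiblast, 3 in place of 13 for PGC minus epiblast, 0 in place of 15 for PGCLC minus PGC and 0 in place of 12 for culture minus embryo step. Without the filter the distance of ESCs was 1.08 to the epiblast and 1.16 to PGCs. Over the 1000 most variable genes, which differ most by construction, distances to the epiblast were 2.92 (ESC), 1.56 (day 2 EpiLC), 2.91 (EpiSC), 3.07 (PGCLC) and 2.88 (PGC), and those to PGCs 3.18 (ESC), 2.98 (day 2 EpiLC), 3.25 (EpiSC), 2.88 (epiblast) and 1.93 (PGCLC).

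Hbb-y reversed in PGC minus epiblast, from -3.08 to 6.11 with the mean of all probe sets and 8.07 with the floor at the 40th percentile, and in PGCLC minus PGC, from 3.22 to -6.04 and -8.07. With the mean of all probe sets the median of nodal targets in day 2 EpiLC minus epiblast went from 0.15 to -0.03 and that of trophoblast markers in EpiSC minus epiblast from 0.05 to -0.07, which is -0.01 with quantile normalization.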

Other observations

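The values below include genes and lists that were picked for description only after their values were seen. Between ESCs and day 2 EpiLCs, glycolysis genes moved apart: of 17, 6 rose, including Slc16a3, at least 24.4-fold, and the phosphofructokinase gene Pfkl, by 2.58 ± 0.21, and 3 fell, including the hexokinase gene Hk1, by 2.03 ± 0.11, while the list did not pass the test (adjusted p = 0.148). Of 21 genes of oxidative phosphorylation 1 was called, Cox7a1, which fell and was chosen after its value was seen, and the list had a median of -0.35 and an adjusted p of 0.00503, with adjusted p = 0.221 with an estimated correlation. Of 20 imprinted genes 6 rose and 2 fell, with Plagl1 lower by -5.76 ± 0.13, without a shift of the list. Of 10 nodal targets 3 rose, Lefty1 by 3.30 ± 0.07, and Lefty2 fell, and of 12 visceral endoderm markers 4 rose and 2 fell. Adjusted over the list alone, the counts of these lists were the same. Compared with ESCs, PGCLCs had 11 of 15 FGF and ERK targets higher and 0 lower, also adjusted over the list alone (adjusted p = 0.122 with an estimated correlation), and 8 of 16 stress genes lower and 1 higher, also adjusted over the list alone (adjusted p = 0.237 with an estimated correlation).

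EpiSCs had 6 of 14 BMP targets higher than day 2 EpiLCs, among them Id1 by 3.16 and Id3 by 2.62 ± 0.15, and 6 of 12 WNT targets, and neither list passed the test. In PGCLCs 5 of 12 neural genes fell against day 2 EpiLCs, Sox1 at least 2.47-fold, again without a shift of the list. Genes of the cell cycle hardly moved: of 17 mitotic genes, 0 were called in day 2 EpiLCs minus ESCs, 1 in EpiSCs minus day 2 EpiLCs (Mki67, higher) and 1 in PGCLCs minus day 2 EpiLCs (Plk1, lower), both chosen after their values were seen. The counts of these lists did not change when adjusted over the list alone.

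Among 4 measured sex-linked genes, Xist, the RNA of the inactive X chromosome, was lower in day 2 EpiLCs than in the epiblast by -2.18 on the log2 scale and was chosen after its value was seen. Its intensity was 97.9 and 63.3 on the epiblast arrays, 33.2 and 39.7 on the PGC arrays and between 14.2 and 24.6 on the amplified arrays of cultured cells. In the list, 2 genes were lower adjusted over the list alone, and it passed the test with an adjusted p of 0.00818 (adjusted p = 0.218 with an estimated correlation). The Y-linked gene Eif2s3y, chosen after its values were seen, was detected in all groups, at 348 and 350 on the epiblast arrays and 575 and 539 on the PGC arrays.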
